A study of Mus musculus with 6 samples.

How the data were processed

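ATAC-seq libraries were made from sorted naive CD8 T cells of mice, 3 labelled Control and 3 labelled DEX, with the Omni-ATAC protocol per the labels' protocols. Each library had a list of peaks in narrowPeak format, and peaks were called per library, as the separate deposited lists show. The submitters' processing notes name cutadapt 1.9.1, Bowtie2 2.3.4.1, SAMtools 1.9, Picard 2.9.0, MACS2 2.1.1 and deepTools 3.1.1, and the builds GRCm38 and mm10, which are the same assembly. They were read here without their order or settings, and whether reads were shifted for the transposase is not given in the sources used here.

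For every peak the deposited lists give the interval, the summit, an integer score, a fold enrichment over the local background, and −log10 of a p-value and a q-value, all made by the authors' peak caller. The smallest −log10 q of the deposited lists lay between 1.30 and 1.31, which fits a q threshold of 0.05. Score, fold and −log10 p are the authors' values of single peaks. They were used to describe, rank or filter peaks within a list. Fold and p were also solved for pileup and background, which gave the background pileups compared between libraries and the scaled and thinned lists.

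Peaks on chromosomes 1 to 19 and X were used, and the 10 to 12 peaks per library on chromosome Y were left out. No rows of a list shared an interval. Because lists of different length cannot be compared peak by peak, each was limited to its 22836 strongest peaks by −log10 p, the length of the shortest. This kept 70.5%, 47.1% and 52.7% of the peaks of Control 1, 2 and 3 and 67.4%, 85.7% and 100% of those of DEX 1, 2 and 3. The weakest peak so kept had a −log10 p of 9.89, 39.2 and 23.3 in Control and 12.5, 6.64 and 3.80 in DEX, so the same rank stands for peaks of different strength. Peaks overlapping by at least 1 bp were merged into 29671 regions, and a region was present in a library with any overlapping peak. Regions present in the 3 libraries of one group and absent from the other were counted and set against the 20 ways to choose 3 libraries.

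Read depth is not given in the sources used here. MACS2 fold enrichment and p-value follow from the pileup and the background at a summit, so they were solved together for 3679 to 4768 summits per library. A whole-number pileup was found, within 0.001 of −log10 p, for 100% of them. The lowest background level (the 0.5 percentile) was taken as the genome-wide background pileup. It grows with the number of reads and with the length given to each read, which is not known here, and is a relative measure of depth.

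Regions were assigned to protein-coding genes of the RefSeq table of GRCm38.p6 (21627 genes). That table gives the start and end of a gene but not its strand, so the planned distance to transcription start sites could not be used. In its place, a region belonged to the gene that contains its midpoint, or else to the nearest gene within 100 kb. Gene ends mean positions within 1 kb of either end of a gene, and exons, introns and UTRs were not told apart. The planned search for motifs of the glucocorticoid receptor and other factors needs the genome sequence and was not run. Of 246 symbols in the 10 gene lists and 6 marker lists, 244 were found in the table.

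Groups were compared by exact permutation of the 6 libraries (two-sided; smallest p 0.1), library similarity by the same splits (one-sided), and shares of regions by Fisher's exact test, with Benjamini-Hochberg adjustment over lists or over the 2 sets. The gene lists, the marker lists, the tests and the alternatives were fixed before the data were examined, except those named here. Lists scaled or thinned to one background, the comparison of background pileups, the gene end shares of control-only and DEX-only regions and the tests of the closing section were added afterwards. For thinning, the reads of each summit with a −log10 p under 200 were drawn at random to the shallowest background, and lists were ranked again and limited to one length, in 20 draws. The genes named were those of the 12 control-only and the 12 DEX-only regions with the best worst rank (the weakest of a region's 3 ranks), passing over regions without a gene. Up to 4 genes per list with a control-only or DEX-only region were added, and Nr3c1, Fkbp5, Tsc22d3 and Per1 were named in any case. Genes with the most regions in all libraries, and examples within lists, were chosen after their values were seen.

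The counting was tested on simulated lists made from the 48531 peaks of the longest list with each library's enrichment, Poisson noise and 1 background pileup of 1.5 for all. With no group effect and lists of 24758 peaks there were 222 control-only and 194 DEX-only regions. Of 200 regions planted per kind anywhere in the list, 41.0% (Control) and 34.5% (DEX) of complete losses in the other group were recovered, 30.0% and 28.5% of 4-fold losses, and 9.00% and 5.50% of 2-fold losses, with 0 in the wrong direction. Planted regions ranked below the length of the lists could not be recovered. Alternatives were whole lists, the 10000 strongest peaks, ranking by fold, a peak covering 50% of a region, summit windows of 200 bp, a −log10 q of at least 5, autosomes alone, a fold of at least 5, other distances to genes (20 kb, or 2.5 kb for gene ends) and each library left out. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.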

Results

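Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse naive OT-I CD8 T cells. OT-I cells carry a transgenic T cell receptor for a peptide of ovalbumin. The cells were sorted from spleen, lymph nodes or both, and came from 3 Control and 3 DEX libraries. DEX is taken here, from knowledge of the study and not from the labels, as dexamethasone, a synthetic glucocorticoid given around birth. On that reading, the question of the design was whether exposure to a stress hormone early in life leaves a lasting mark on the chromatin of these cells. The labels do not say that the libraries came from separate animals, so the permutation p-values below measure the spread between these libraries, which may be technical. Fisher's exact tests over regions treat regions as units and measure no spread between libraries. With 3 libraries against 3, the smallest two-sided exact permutation p is 0.1, so no comparison of the groups by this test can pass 0.05.

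Of 29671 regions with a peak among the 22836 strongest of any library, 16458 (55.5%) had a peak in all 6. With the lists as deposited, which differ in length, 18480 of 55498 regions had a peak in all 6. The genes with the most such regions were Bach2, Foxp1 and Prkcq, with 17 each. Bach2 encodes a repressor that restrains effector differentiation, Foxp1 a forkhead factor of T cell quiescence, and Prkcq a protein kinase C of T cell receptor signalling. Akap13 had 16, and Arhgef3, Chd7 and Ets1 had 14 each. Lef1, a transcription factor of naive T cells, had 13, as did Btg1, Ppm1h and Prkch. These counts per gene come from the lists of one length. They were not adjusted for the length of the gene or of the sequence around it, so they do not rank genes by openness.

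The deposited lists themselves differed in length, and the longest were from Control libraries. Control libraries held 32406, 48531 and 43367 peaks on chromosomes 1 to 19 and X, a mean of 41435 ± 8234 (SD, n = 3). DEX libraries held 33883, 26653 and 22836, a mean of 27791 ± 5611 (SD, n = 3). The difference was -13644 peaks for DEX minus Control (exact permutation p = 0.2, two-sided), and DEX 1 had more peaks than Control 1. Peaks covered 19.2 ± 5.14 Mb in Control and 11.3 ± 3.00 Mb in DEX (SD, n = 3, exact permutation p = 0.2). The background pileup, a relative measure of depth recovered from the peak values, was 1.62, 1.86 and 1.59 reads over a position in Control. It was 1.39, 1.44 and 1.29 in DEX, so every Control library lay above every DEX library. Group means were 1.69 ± 0.15 and 1.37 ± 0.0802 (SD, n = 3, exact permutation p = 0.1, the smallest possible). With pileups scaled to the shallowest background, a setting added after seeing the data, the difference was -12266 peaks (exact permutation p = 0.2). Among the 22836 strongest peaks of each library, peaks covered 13.8 Mb in Control and 10.1 Mb in DEX (exact permutation p = 0.2).

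**Figure D1:**
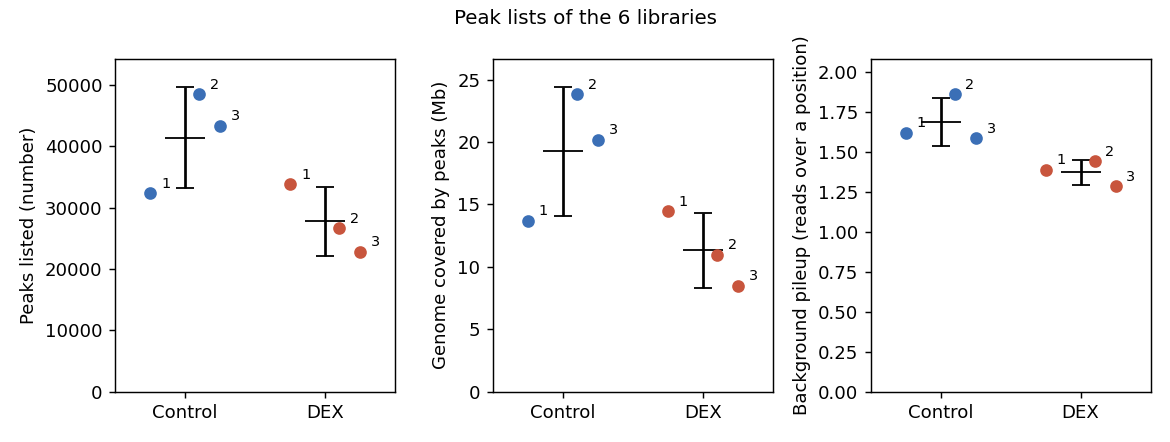
Peaks listed, genome covered by peaks in Mb, and background pileup in reads over a position, for each library; points are libraries with their replicate numbers, and bars show the mean ± SD of the 3 libraries of a group. Background pileup separates the groups (at least 1.59 in Control, at most 1.44 in DEX), while DEX 1, with 33883 peaks, lies above Control 1, with 32406.

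Regions with a peak in every Control library and no DEX library were called control-only, and those with the reverse pattern DEX-only. There were 200 control-only and 60 DEX-only regions. The control-only regions with the strongest ranks lay in Uggt2, in Ccnd2, which encodes cyclin D2, and in Akna, which encodes an AT-hook factor. The region in Uggt2 was on chromosome 14 at 119027154 to 119027593 (GRCm38), that in Ccnd2 on chromosome 6 at 127147759 to 127147978, and that in Akna on chromosome 4 at 63391289 to 63391783. All 3 lay inside the gene body and were absent from the whole lists of all DEX libraries. Next came regions near Lpin1, a phosphatidate phosphatase, in Gabrr3 and near Dand5, and these 3 were each listed in the whole list of DEX 1. A region in Prkcb, the gene of protein kinase C beta, was absent from all DEX lists, as were regions near Tubgcp3 and Trpm4 and in Ttc28. Trpm4 encodes a calcium-activated cation channel. The regions in Serinc5 and Gstt1 were listed in the whole lists of DEX 1 and DEX 2.

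Among the genes of the lists fixed before the data were examined, Ifng, the gene of the effector cytokine interferon gamma, had 2 control-only regions. The first, on chromosome 10 at 118440603 to 118441081, spans the low-coordinate end of the gene and was listed in the whole list of DEX 1. The second, at 118477297 to 118477727, is intergenic, 31618 bp from the gene, and was absent from all DEX lists. Ifng had 9 assigned regions in all, of which 4 had a peak in all 6 libraries. Single control-only regions absent from all DEX lists lay in Klf9, a glucocorticoid-induced transcription factor gene, in Itgae, near Ccr7, near Cd6, near Tgfbr2 and in Epor. Ccr7 encodes the lymph node homing receptor, Cd6 a surface receptor that tunes T cell activation, and Itgae the alpha E integrin. Regions near Cd8b1, which encodes the CD8 beta chain, in Ifngr1 and near Actb were control-only but listed in the whole list of DEX 1. The Klf9 region was on chromosome 19 at 23151503 to 23151986, and the Ccr7 region on chromosome 11 at 99130810 to 99131009, 13289 bp from the gene.

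**Figure D2:**
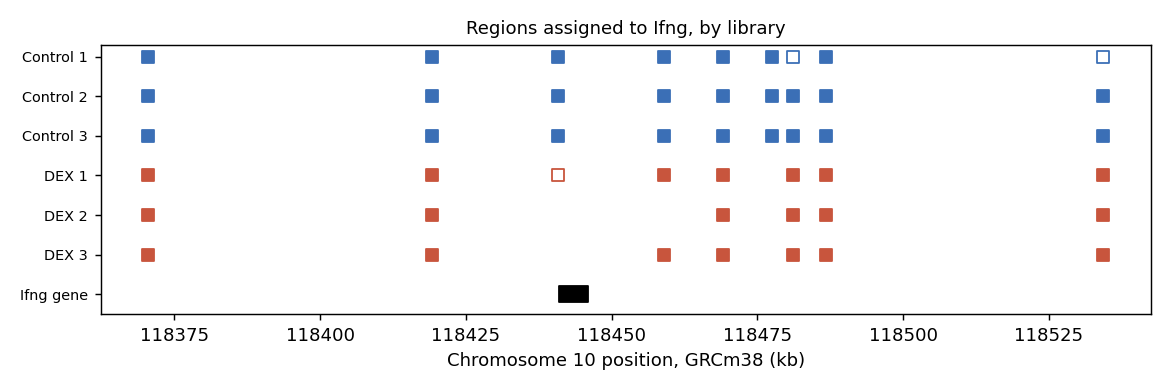
The 9 regions assigned to Ifng along chromosome 10 (GRCm38, position in kb), by library; filled squares mark a peak among the 22836 strongest of the library, open squares a weaker peak of its whole list, and the black bar is the gene from 118441046 to 118445894. Squares mark the middle of each region and are wider than the region. The regions at 118440603 and 118477297 have filled squares in the 3 Control libraries only, and 4 regions have filled squares in all 6.

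DEX-only regions with the strongest ranks lay in Pip4k2a, a phosphoinositide kinase gene, near Btg1, an antiproliferative gene of T cell quiescence, and near Icosl, which encodes the ligand of ICOS. A DEX-only region at an end of Ptprc, the gene of CD45, was on chromosome 1 at 138174846 to 138175347. The region in Pip4k2a was on chromosome 2 at 18938913 to 18939278 and that near Btg1 on chromosome 10 at 96663518 to 96663846. Others lay in Sh3bp1, Wasl, Npc1, Cds2 and Prkce, at ends of Slc23a2 and Limd1, and 85478 bp from Il12a. Of the naive T cell genes, Bach2 and Igfbp4 each had a DEX-only region. The whole Control lists held all of these regions. Pip4k2a, Icosl, Ptprc and Il12a were in those of Control 2 and Control 3, Sh3bp1 in that of Control 1, and the rest in those of all 3 Control libraries.

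For no single region could the difference pass a threshold, since Fisher's exact test of 3 against 3 libraries has a smallest p of 0.1. Of the 200 control-only regions, 68 were absent from the whole lists of all DEX libraries, 100 were in 1 of them and 32 in 2. All 60 DEX-only regions were in at least 1 whole Control list, and 40 were in all 3. The limited list of DEX 3 was its whole list, so no control-only region could be in all 3 whole DEX lists. Whole lists reached 48531 peaks in Control and 33883 in DEX. Presence in the whole lists of the other group therefore depends on list length, also for the genes named above. With each region ranked by its weakest list position of 3, the best rank was 15620 of 22836 for control-only and 16094 for DEX-only regions. Other choices of 3 libraries gave between 46 and 295 regions, and the 295 were those of Control 2, Control 3 and DEX 1. With the lists as deposited, the numbers were 1703 control-only and 0 DEX-only, against 2980 for Control 2, Control 3 and DEX 1. Among the 10000 strongest peaks they were 48 control-only and 40 DEX-only. These are other regions than the 200 and 60, whose best rank lay beyond 10000. Without DEX 3, the library with the lowest background pileup, the numbers were 301 and 220. Lists simulated with no group effect held 222 control-only and 194 DEX-only regions. They were longer (24758 peaks) and had 1 background and the same peak intervals for all libraries.

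**Figure D3:**
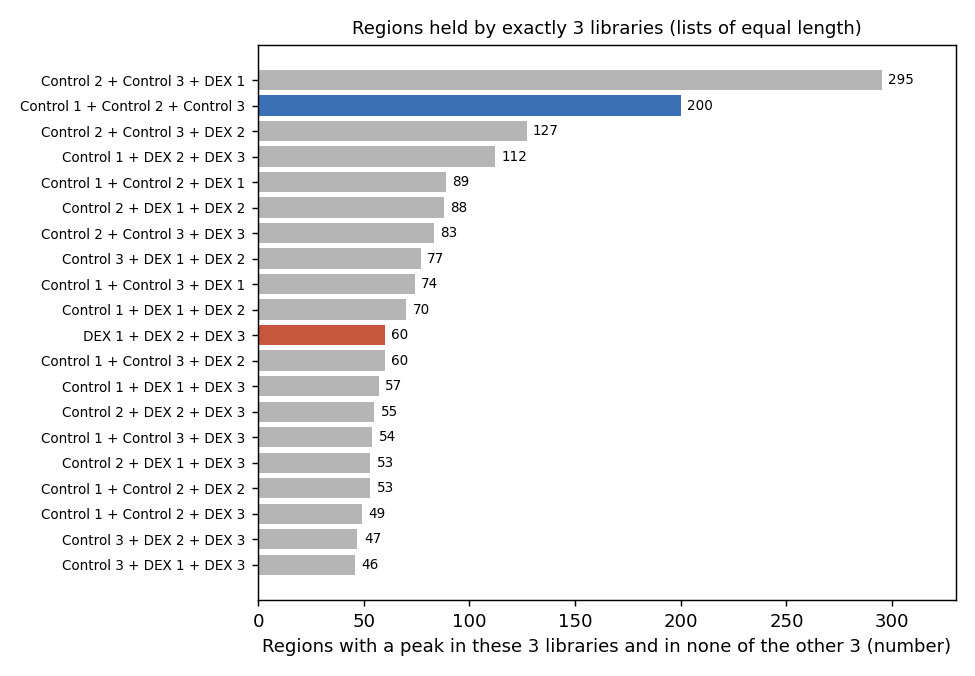
Number of regions with a peak in the 3 named libraries and in none of the other 3, for each of the 20 ways to choose 3 of 6 libraries. The 3 Control libraries (blue) hold 200 such regions and the 3 DEX libraries (red) 60, while Control 2, Control 3 and DEX 1 hold 295.

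The regulators and classical targets of the glucocorticoid response had open regions in both groups, with a region in all 6 libraries at 15 of 17 genes of the list and none in any library at Mt2 and Zbtb16. All 3 regions of Per1, a clock gene induced by glucocorticoids, had a peak in all 6 libraries. Of the 4 regions of Nr3c1, which encodes the glucocorticoid receptor, 3 were in all 6 libraries, the 1 at a gene end on chromosome 18 at 39518929 to 39519994 included. Fkbp5, which encodes a co-chaperone of the receptor, had 7 regions and Tsc22d3, the gene of the leucine zipper protein GILZ, had 6, of which 3 each were in all 6 libraries. None of the regions of these 4 genes was control-only or DEX-only. The list of glucocorticoid-responsive genes held 58.0 ± 2.65 regions per Control library and 59.0 ± 2.65 per DEX library (SD, n = 3, exact permutation p = 0.6). Cxcr4, the chemokine receptor of bone marrow homing, had 10 of its 12 regions in all 6 libraries, and Sgk1 and Bcl2l11 had 6 of 8 each.

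Genes of the naive state had many open regions in both groups. The naive T cell list held 203.3 ± 2.52 regions per Control library and 201.0 ± 11.5 per DEX library (SD, n = 3, exact permutation p = 0.9), and 19 of its 20 genes had a region in all 6 libraries. Foxp1 had 36 regions, Bach2 29, Lef1 25 and Tcf7 12. Effector and memory genes held 84.7 ± 3.06 and 80.3 ± 2.31 regions (SD, n = 3, exact permutation p = 0.2). Of 26 such genes, 22 had a region in all 6 libraries, among them Prf1, which encodes perforin, with all 3 of its regions. Gzma and Gzmk had no region in the lists of one length, and weaker peaks of the whole lists were not examined for them. Activation and inhibitory receptor genes, such as Tox with 8 and Cd69 with 6 regions in all 6 libraries, held 65.3 ± 1.53 and 61.7 ± 3.21 regions (SD, n = 3, exact permutation p = 0.2).

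T cell receptor signalling genes held 153.0 ± 6.25 regions per Control library and 152.7 ± 1.53 per DEX library (SD, n = 3, exact permutation p = 1). Cytokine receptor and JAK-STAT genes held 138.7 ± 6.66 and 131.3 ± 5.51 (SD, n = 3, exact permutation p = 0.3). Tgfbr2, a receptor of TGF beta, had 15, 18 and 16 regions in Control and 16, 11 and 13 in DEX, so the groups overlapped. Other genes of the list went the other way, such as Il6st with 8.67 against 9.33 on average. Chemokine receptor and adhesion genes held 79.7 ± 1.15 in Control and 75.7 ± 2.08 in DEX (SD, n = 3, exact permutation p = 0.1, the smallest possible; 0.686 after Benjamini-Hochberg adjustment over 16 lists). Every Control library lay above every DEX library in this list, and S1pr1, the receptor of lymph node exit, had 13.7 regions on average in Control and 12 in DEX. Interferon-stimulated genes held 21.0 ± 1.73 and 19 ± 1.00 (SD, n = 3, exact permutation p = 0.3), AP-1 family genes 28.0 ± 1.73 and 28.0 ± 1.00 (SD, n = 3, exact permutation p = 1). Housekeeping genes held 36.7 ± 3.21 and 34.0 ± 1.00 (SD, n = 3, exact permutation p = 0.4).

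Markers of other cell types had between 4 and 17 regions per list. These counts come from the lists of one length, so a marker with none may have a weaker peak in a whole list. The B cell list held 10 regions, 7 ± 1.00 per Control and 5.67 ± 3.06 per DEX library (SD, n = 3, exact permutation p = 0.6), and Cd79a, Cd79b and Ms4a1 had none. The myeloid list held 9 (7.33 ± 0.577 against 6.33 ± 1.15, SD, n = 3, exact permutation p = 0.6), with 4 at Itgam, 3 at Spi1 and none at Lyz2, Csf1r or Adgre1. NK cell markers held 17 (10.3 ± 1.15 against 10 ± 2.65, SD, n = 3, exact permutation p = 1), with 8 at Klrb1c and none at Ncr1. CD4 and regulatory T cell markers held 16 (11 ± 2.00 against 11 ± 1.00, SD, n = 3, exact permutation p = 1), with 7 at Ikzf2, 6 at Cd40lg and none at Foxp3. Gamma-delta and innate-like T cell markers held 13 (8 ± 1.00 against 9.33 ± 1.15, SD, n = 3, exact permutation p = 0.3). Erythroid markers held 4 (3.67 ± 0.577 against 2.67 ± 0.577, SD, n = 3, exact permutation p = 0.3), with none at Alas2.

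Over the 10 gene lists and 6 marker lists, 12 had a lower mean in DEX, 2 a higher mean and 2 the same mean. Some lists share genes, and over all regions too, Control libraries mostly held more than DEX libraries. In the most unequal pair, Control 2 had 4192 regions that DEX 3 lacked, and DEX 3 had 2997 that Control 2 lacked. Only Control 1 against DEX 1 went the other way, with 2606 and 2788. The 12 lists therefore do not set these genes apart from regions at large. The smallest adjusted p over the 16 lists was 0.686, so no list was called. No list was over-represented among control-only or DEX-only regions against other regions held by exactly 3 libraries (Fisher's exact test, adjusted p = 1 for every list in both directions; 0 of the 32 tests had an unadjusted p under 0.05). The interferon-stimulated, AP-1 family and NK cell lists had 0 regions in exactly 3 libraries, so the outcome of their Fisher tests was fixed. Other lists had few such regions, at most 16 (naive T cell genes), so these tests could find only large shifts. With the lists as deposited all 16 lists had a lower mean in DEX. In the 10000 strongest peaks 7 lists had a lower mean in DEX and the difference of 6 lists changed sign. Ranked by fold enrichment the difference of 7 lists changed sign, that of chemokine receptor and adhesion genes to 5 regions more in DEX included.

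**Figure D4:**
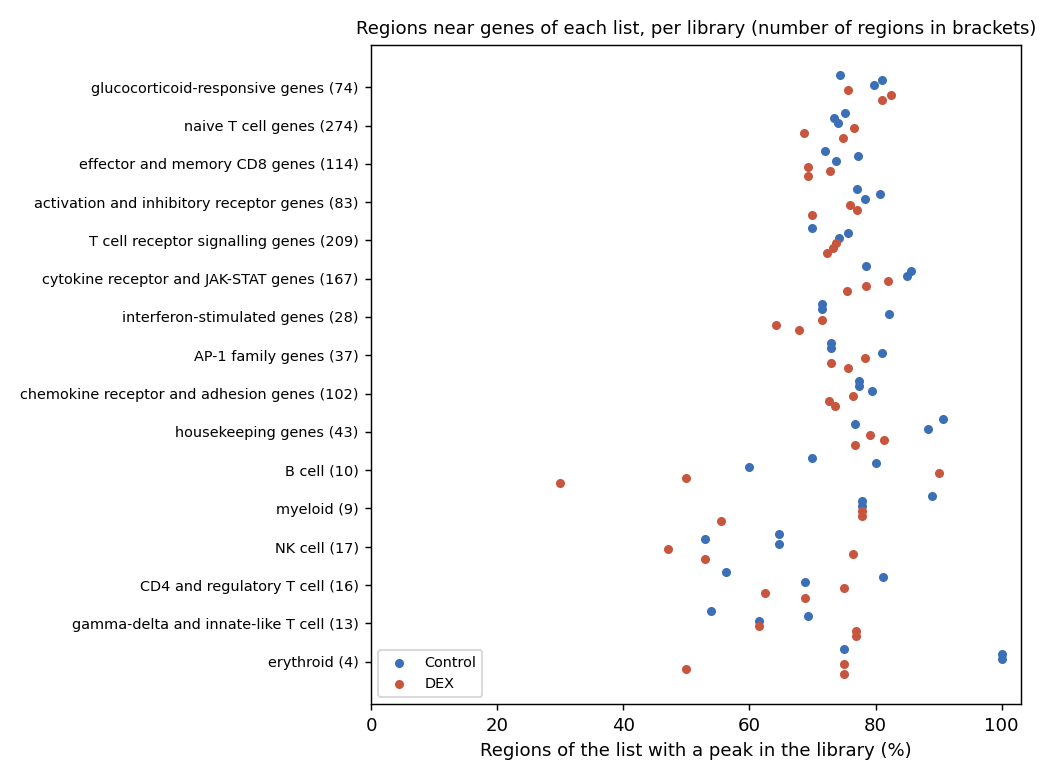
Share of the regions of each list with a peak among the 22836 strongest of the library, in percent, for the 10 gene lists and the 6 marker lists; each point is a library, offset vertically by replicate so that equal values stay visible, and the number of regions is in brackets. Points of the 2 groups overlap in most lists, and in chemokine receptor and adhesion genes the Control libraries hold 79, 79 and 81 of 102 regions and the DEX libraries 78, 74 and 75.

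Summits of the strongest peaks within 1 kb of either end of a protein-coding gene made up 37.7 ± 1.43% of the peaks in Control and 38.9 ± 1.31% in DEX (SD, n = 3, exact permutation p = 0.4). Summits elsewhere in gene bodies made up 36.7 ± 0.880% and 36.3 ± 0.697% (SD, n = 3, exact permutation p = 0.5), and intergenic summits 25.6 ± 0.554% and 24.9 ± 0.615% (SD, n = 3, exact permutation p = 0.2). Regions present in all 6 libraries were at gene ends in 45.4%, against 11.5% of control-only and 13.3% of DEX-only regions. Other regions held by exactly 3 libraries were at gene ends in 17.1% for the first comparison (Fisher's exact test, p = 0.0431, adjusted p = 0.0862) and in 16.6% for the second (p = 0.598, adjusted p = 0.598). In the 10000 strongest peaks the difference between the groups in the share at gene ends was -0.960 percentage points for DEX minus Control, against 1.11 with the 22836 strongest. With the lists as deposited the share of control-only regions at gene ends lay 6.59 percentage points above that of other regions in exactly 3 libraries (p = 3.2e-11), the reverse of the difference above. Ranked by fold, control-only minus other regions was -11.2 percentage points (p = 1.04e-06, both by Fisher's exact test over regions, unadjusted). Regions are not replicates. In the lists of one length, the share at gene ends in other sets of 3 libraries ran from 4.82% to 40.2%, and the 11.5% of control-only regions lies within this range.

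The accessible sequence shared by libraries of one group was compared with that shared by libraries of different groups. The mean Jaccard index, the shared length divided by the total length, was 0.665 within groups and 0.617 between groups. The difference of 0.0486 was reached by 2 of the 10 splits of the 6 libraries (exact permutation p = 0.2, one-sided), and the highest other split, Control 1, DEX 2 and DEX 3 against the rest, gave 0.0629. Control 2 and Control 3 were the most alike, at 0.784, and Control 2 and DEX 3 the least, at 0.485. The index is in bp and so depends on the width of the peaks as well as on shared sites. The limited lists covered 15.5 Mb in Control 2, 14.2 Mb in Control 3 and 8.50 Mb in DEX 3, which by itself lowers the index of the last pair. Without Control 2 the difference was 0.00655, and without Control 3 it was 0.0168. In summit windows of 200 bp it was 0.0124.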

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

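The lists scaled or thinned to one background, the background pileups and the comparison of gene ends in control-only and DEX-only regions were added after seeing the data; the other settings were fixed before. The difference in peaks per library kept its sign in all settings, from -10096 to -18158 peaks with a library left out, and the similarity difference stayed above 0, from 0.00655 to 0.102, with 0.0124 in summit windows. The exact permutation test cannot pass 0.05 with 3 libraries a side, so its p-values say nothing about stability. The counts of regions depended on the length of the lists. Control-only and DEX-only regions numbered 1703 and 0 in the lists as deposited, 1389 and 0 in those lists with a −log10 q of at least 5, and 1402 and 0 in the scaled lists. They numbered 68 and 0 when absent from whole lists was asked, and 749 and 32 when a peak had to cover 50% of a region. They numbered 48 and 40 among the 10000 strongest peaks, and these are other regions than the 200 and 60. Counts were 297 and 169 when ranked by fold, 219 and 120 in summit windows, and 181 and 70.4 (means of 20 draws) in thinned lists. With a library left out, fewer libraries have to agree, and control-only regions numbered 301 (without DEX 3) to 658 (without DEX 1) and DEX-only regions 120 (without Control 3) to 249 (without DEX 1). The excess of control-only regions was least without DEX 3, at 301 against 220.

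Differences between groups are DEX minus Control, and the cause of each change of sign was not tested. The share at gene ends changed from 1.11 to -0.960 percentage points among the 10000 strongest peaks. Against other regions in exactly 3 libraries, the share of control-only regions at gene ends differed by -5.61 points, by 6.59 in the lists as deposited, 5.63 among the 10000 strongest and -11.2 ranked by fold, and that of DEX-only regions by 0.205 ranked by fold. Among the 10000 strongest, 7 lists were lower in DEX, and the differences were -1 region for glucocorticoid-responsive, 3.00 for naive, 1.00 for activation, 5.67 for T cell receptor, 3.33 for cytokine receptor and 3.67 for housekeeping genes. Ranked by fold they were 34.0 for naive, 1.00 for activation, 32.7 for T cell receptor, 22 for cytokine receptor, 5 for chemokine receptor and 3.67 for housekeeping genes, and -0.333 for gamma-delta markers. As deposited all 16 lists were lower in DEX, with -31.0 for glucocorticoid-responsive genes and -11.0 for gamma-delta markers, and within 20 kb 2.00 for naive genes. With a library left out, the differences ran from -0.5 (without Control 1) to 2.5 for glucocorticoid-responsive, from -6.83 to 4.17 (without DEX 2) for naive and from -3.83 to 2.17 (without Control 2) for T cell receptor genes, and from -1.83 to 0.667 (without DEX 1) for NK cell markers.

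In the lists as deposited with a −log10 q of at least 5, and so not of one length, more Control than DEX libraries held the DEX-only regions of Igfbp4 and Bach2 (by 2) and of Prkce, Npc1, Slc23a2 and Cds2 (by 1). Among the named regions, 14 of 23 control-only and 0 of 14 DEX-only ones kept 3 libraries against 0 in the lists as deposited, which hold 0 DEX-only regions in all. Ranked by fold 10 and 7 did. Among the 10000 strongest 0 and 0 did, which was fixed in advance. The best rank, taken as the weakest of 3, was 15620 for control-only and 16094 for DEX-only regions. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.105, -0.0122 and -0.0498 across regions, and 0 of 6 libraries correlated best with their own number. With the number as a block, only the permutations change. The exact permutation p was 0.5 for the peak difference of -13644 (smallest 0.25) and 0.5 for the gene end difference of 1.11. The differences, the counts of 200 and 60 and the 12 lists lower in DEX cannot move under this setting. Motif alternatives were not run, and a 50% cover has no counterpart for the similarity in bp. Depth limits what absence means, since a region absent from a list may have been below its threshold: 132 of 200 control-only regions had a peak in the whole list of a DEX library, and 68 had none.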

Other observations

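All tests below were added after the data were first examined. Those on thinned lists, on the 3 longest lists, on the splits of the libraries, on the Ifng regions in scaled lists and on the largest other set of 3 libraries were chosen after the results were seen. For the other tests the bounds were written before the test was run. Themis, which encodes a regulator of T cell receptor signalling in thymocytes, had 1 region in each Control library and 3, 2 and 4 in the DEX libraries. S1pr1 had 13, 14 and 14 regions in Control and 12 in each DEX library, Itgae 3 against 2, and Epor 1 against 0. These 4 genes, chosen after their values were seen, were the ones whose counts of regions did not overlap between the groups among 209 list genes with a region (1.91%; chance gives 10% for values without ties, and these counts are often tied). The highest other split gave 11 such genes, and 4 of 10 splits gave at least 4.

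More regions were held by every Control and no DEX library (200) than the reverse (60). The excess was smaller among the 10000 strongest peaks, in other regions (48 against 40), and without DEX 3 (301 against 220). Without DEX 1 it was 658 against 249, and without DEX 2 393 against 170. Lists simulated with no group effect gave 222 against 194. They were longer, had 1 background and the same peak intervals for all libraries, and were not drawn repeatedly. They therefore cannot show what excess arises without a group effect in lists that differ in peak width and background. Whole lists scaled to the shallowest background gave 1402 and 0. The bound set for this test was wrong, since the unscaled lists already gave 1703 and 0. A second test of depth thinned the reads to that background in lists of one length. The ratio was then 2.58 against 3.33 (lowest of 20 draws 2.04, near the bound of 2). Thinning changed the strength of peaks but not their intervals, which covered 13.8 Mb in Control and 10.1 Mb in DEX. In summit windows of 200 bp, not thinned, the counts were 219 and 120. The thinning therefore cannot decide whether depth is the whole cause, and depth stays open. Lists of unequal length and enrichment whatever the group may account for the excess of control-only regions: the 3 longest lists, Control 2, Control 3 and DEX 1, shared 295 regions absent from the others. As many regions confined to one side as in the study's groups (260) were found in 2 of 10 splits, and 10 splits are too few for a share under 0.05. The highest other split, with 407, parts the 3 longest from the 3 shortest lists. It includes the 295 regions above, so both counts are 1 observation, which points to a structure of the samples by list length. An effect of DEX treatment stays open and was not separable from these, as the 3 longest lists hold 1 DEX library and the 3 shortest 1 Control library.

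Regions held only by the 3 shortest lists, Control 1, DEX 2 and DEX 3, were at gene ends in 40.2%, against 9.15% for those held only by the 3 longest. This concerns the lists of one length, since 1 region was confined to the 3 shortest and 2980 to the 3 longest in the lists as deposited. Over all sets of 3 libraries, the shares ran from 11.5% to 40.2% with Control 1 and from 4.82% to 19.6% without it. Control 1, Control 3 and DEX 3 gave 37.0%. A trait of Control 1 therefore cannot be told apart from one of the short lists. Weak peaks at the end of the short lists may account for part of the contrast between shortest and longest lists. The contrast remained, smaller, with peaks ranked beyond 10000 left out. A limit of 10000 makes a new list end, so this test cannot decide whether the end of the lists is the whole cause. Among the 10000 strongest peaks the ratio of the shares fell from 4.39 to 2.45 (52.5% against 21.4%, Fisher's exact test p = 0.000940, over regions, which are not replicates). Both shares rose, so the lower ratio does not show how large a part weak peaks have. There the shares ran from 26.3% to 70% in sets with Control 1 and from 20% to 44.8% in sets without it. A candidate explanation is that enrichment at gene ends relative to other open regions differed between preparations, but no test of this was run. The study's groups do not follow this division, so no biological explanation was tested.

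Ifng and 6 other genes (Actn1, Ier5, Nod1, Panx1, Timm10 and Ttc28) each had at least 2 control-only regions. Shuffles argue against chance meeting alone, with as many such genes in 0.0261 of 10000 and a mean of 2.94, but Control was 1 of 20 sets of 3 libraries that could be asked, and neighbouring regions are not independent. Whether neighbouring regions go together in any libraries cannot be told apart, because only 1 other set was as large: Control 2, Control 3 and DEX 1 had 9 such genes (share of shuffles 0.168). Depth cannot be told apart either for Ifng: 1 of its 2 regions was confined to Control in the scaled lists, but scaling moved 0 of its 9 regions, so this test could not decide. An effect of DEX treatment at Ifng stays open and was not tested; 4 of its 9 regions had a peak in all 6 libraries, and 1 was absent from all whole DEX lists.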
